A study of Mus musculus with 48 samples.

How the data were processed

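The series holds 48 samples of sorted mouse inner ear cells in 23 groups. RNA-seq covers 6 libraries, 3 of hair cells and 3 of supporting cells from the cochlea at postnatal day 1 (P1). The other 42 samples are peak lists in 21 groups of 2 libraries each, from ATAC-seq (accessible chromatin), ChIP-seq and CUT&RUN (an antibody-directed nuclease releases the marked chromatin). Hair cells, the sensory receptor cells, were sorted by a green fluorescent reporter of Atoh1, and supporting cells, the non-sensory neighbours, by a reporter of Lfng, per the labels. The cell types thus came from different reporter lines, so a difference between them cannot be told apart from a difference between the lines. Supporting cells were taken at E17.5 (days of gestation) and at P1, P6 and P21 from the cochlea, at P1 also from its apical and its basal part, and at P21 also from the utricle (a vestibular organ). Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

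Per the labels' protocols, RNA libraries were made from poly-A RNA, ChIP-seq chromatin was fixed with formaldehyde, sonicated and tagged by Tn5, and CUT&RUN libraries of histone marks carried adaptors with molecular identifiers. ATOH1 CUT&RUN used an antibody against green fluorescent protein in cells with an ATOH1 fusion protein, per the labels. The submitters' processing notes name STAR, RSEM, DESeq2, Bowtie2, MACS2, UMI-tools and the mm10 genome, with no role or version. The deposited RNA-seq tables hold expected counts per gene and library, which are estimates and need not be whole, per the file headers. The same deposited tables hold TPM (transcript abundance scaled to a common total within each library by the authors), per the file headers. The deposited peak lists hold, for each peak, a -log10 q against the peak caller's background, made by the authors for 1 library at a time. The control, threshold, read shift and blacklist of the peak calling are not given in the sources used here. The peak lists held between 14163 and 887135 peaks, and the lowest -log10 q in a list lay between 0.1311 and 2.7, so lists differ in length and stringency. Read depth behind the peak lists is unknown here, and no read coverage was used. H3K27ac was measured by ChIP-seq in hair cells and by CUT&RUN in supporting cells, and H3K4me3 by ChIP-seq in P1 hair cells and E17.5 supporting cells and by CUT&RUN in P1 and P6 supporting cells.

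The RNA-seq tables list 48709 genes by Ensembl identifier. Symbols were matched for 41341 identifiers with their version and for 48349 with or without it. Total expected counts were 15615174, 14349969 and 14398295 in hair cell replicates 1 to 3 and 11634513, 13953456 and 12260780 in supporting cell replicates 1 to 3. Replicates of 1 group differed by more than sampling noise, with chi-square per degree of freedom between 11.4 and 36.9, so no library was counted as a copy of another. Expected counts were rounded to whole numbers, genes with low counts were removed with the default filter of edgeR, and 15652 genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2, hair cells minus supporting cells, with standard errors (SE), and levels are CPM (counts scaled to a common total per library) with TMM factors. Enriched genes have an adjusted p under 0.05 and a log2 fold change beyond 1 in size. The fit was tested on simulated data with 200 changed genes among 15394: it recovered 70% of the 2-fold and 95% of the 4-fold changes, with 20 false calls.

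The 21 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, again at a correlation estimated from the data, and with fry, each adjusted over the 21 lists. Genes named in the text follow a rule: Atoh1 and Lfng as the reporter genes, up to 4 members of each list with the largest change past the test, and the 10 genes with the largest change in each direction with a mean of 20 CPM or more in the higher group and no overlap between groups. At listed loci, the elements nearest to the gene were counted, and those of loci with elements are given with coordinates. The results of some genes that the rule names are not reported here. The gene lists, the naming rule, the element sets, the tests and most of the other settings tried were fixed before the data were examined.

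Element sets were built on mm10 from the deposited peak lists. A region was accessible in a cell type where both P1 ATAC-seq replicates held a peak, distal where it overlapped no H3K4me3 region held by both replicates of P1 hair cells or of P1 supporting cells, and active where it overlapped an H3K27ac peak in each replicate. Hair-cell-specific elements had no ATAC-seq peak over the region itself in either P1 supporting cell library, supporting-cell-specific elements had none in either P1 hair cell library, and shared elements were accessible and active in both cell types. An element counted as marked in a library where a peak overlapped its midpoint plus and minus 500 bp by 1 bp or more. The value of a library is the percentage of each set marked, with 95% Wilson intervals that cover counting error only, and the log2 odds ratio of hair-cell-specific against shared elements, with 0.5 added to each count. The same windows moved by 1 Mb gave the background share. The sets were chosen from P1 accessibility, H3K27ac and H3K4me3, so a contrast of P1 hair cells with P1 supporting cells over them is not independent of that choice. Nor is a contrast of the sets across stages of supporting cells, since the sets differ by definition in P1 supporting cells.

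Library values were compared by exact permutation of library labels, two-sided, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A comparison of 2 against 2 libraries has 6 assignments and cannot give a p below 0.33. A trend over 3 stages has 90 assignments and a smallest p of 0.022, and a trend over 4 stages has 2520 and a smallest p of 0.00079. Trends used Pearson and Spearman correlations with stage order. The 7 comparisons of element marking form 1 family for Benjamini-Hochberg adjustment. Overlap with ATOH1 regions and nearness to enriched genes were compared between element sets with Fisher's exact test, two-sided, in which elements are not replicates of the cells. The odds ratio was tested on 200 draws of simulated counts, sized as the hair-cell-specific and supporting-cell-specific sets. With a true log2 odds ratio of -4.0 the mean recovered was -4.00, with an SD of 0.134. A comparison set near saturation, as the shared set is, was not simulated. Figures were drawn with matplotlib 3.10.9.

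The annotation used here (GRCm38.p6, the same build as mm10) gives gene extents without strand, so transcription start sites were not used. The planned start site windows were replaced by windows of 1 kb to each side of either gene end, and an element was linked to the protein-coding gene whose extent lay nearest within 100 kb. Of 21631 protein-coding genes on chromosomes 1 to 19 and X, 13307 had a tested RNA-seq gene. H3K27me3 lists hold peaks on the 19 autosomes only, so their tests leave out chromosome X. Exon and intron annotation was not used here, and RNA-seq of supporting cells at E17.5 and P6 was not analysed here.

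Alternatives for RNA-seq were DESeq2 1.42.0 with its own size factors, RLE factors, no filter on low counts, the replicate number as a block, each library left out in turn, limma-trend on log2(TPM + 1) over genes with a mean TPM of at least 1, and a fold change minimum. Alternatives for peaks were stricter -log10 q minimums of 2 and 5, lists of equal length, other windows, overlap of the region itself, coverage of at least 50% of the window, elements without the H3K27ac criterion, distance of 2 kb from gene ends, the supporting-cell-specific set for comparison, percentages in place of odds ratios, and each library left out in turn. Further alternatives were chosen after seeing the data: percentages combined with those settings, another reading of the shared set, and the supporting-cell-specific set with lists of equal length. The replicate block for ATOH1-bound elements and H3K4me3 was also chosen then.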

Results

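The study profiled hair cells and supporting cells of the mouse cochlea around birth, and supporting cells of the cochlea and utricle at P21, to follow the chromatin state of hair cell regulatory elements in supporting cells as they mature. RNA-seq compared 3 libraries of P1 hair cells, with 14349969 to 15615174 counts each, with 3 of P1 supporting cells, with 11634513 to 13953456. Peak lists of accessible chromatin (ATAC-seq), H3K4me1 (a mark of enhancers), H3K4me3 (promoters), H3K27ac (active elements), H3K27me3 (Polycomb repression) and the transcription factor ATOH1 came from 2 libraries per group. Correlations of log2 expression lay between 0.9803 and 0.9869 within RNA-seq groups and between 0.9036 and 0.9333 across them.

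The comparison of P1 hair cells with P1 supporting cells asked which genes each cell type expresses. The reporter genes followed the sort. Atoh1 (ENSMUSG00000073043.5), which drives hair cell fate, averaged 168 ± 15.8 CPM (SD, n = 3) in hair cells and 50.3 ± 11.4 CPM in supporting cells, a log2 fold change of 1.74 ± 0.15 (SE, edgeR adjusted p = 3.09e-05). Lfng, which encodes a glycosyltransferase that modifies Notch receptors, averaged 132 ± 7.85 CPM in hair cells and 1787 ± 203 CPM in supporting cells, a log2 fold change of -3.75 ± 0.12 (edgeR adjusted p = 6.9e-07). Of 15652 genes tested, 4104 (26.2%) were higher and 4121 (26.3%) lower in hair cells, and 7427 did not pass the threshold. With a log2 fold change beyond 1 as well, 1407 were higher and 2093 lower.

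Hair cell transcription factors and regulators rose together in hair cells: all 11 tested members were higher, 11 also when adjusted over the list alone. Neurod6 changed by 2.62 ± 0.28 (log2, SE), Insm1 by 1.87 ± 0.12, Atoh1 by 1.74 ± 0.15 and Nhlh1 by 1.70 ± 0.14, and Pou4f3, needed for hair cell survival, by 1.58 ± 0.11. The list passed camera (adjusted p = 8.66e-07), and the call was lost with adjusted p = 0.412 with an estimated correlation. Of 32 genes of mechanotransduction and stereocilia, 30 were higher, 1 lower and 1 not past the threshold, with 30 higher and 1 lower adjusted over the list alone. The tip link cadherins Pcdh15 and Cdh23 changed by 1.67 ± 0.10 and 1.59 ± 0.10, and Ptprq by 1.53 ± 0.17. Ush1c, which encodes the scaffold harmonin, went the other way (144 CPM in hair cells, 288 CPM in supporting cells), and Eps8 had -0.08 ± 0.09. This list had a camera adjusted p = 9.18e-10 and adjusted p = 0.467 with an estimated correlation.

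Of 19 genes of the hair cell synapse and excitability, 18 were higher, 18 also adjusted over the list alone. The efferent acetylcholine receptor gene Chrna9 changed by 1.55 ± 0.17, the calcium buffer gene Calb1 by 1.49 ± 0.17 and Slc26a5, which encodes prestin, by 1.49 ± 0.23, and the potassium channel gene Kcnn2 stood at 41.0 CPM against 14.6. Ocm, at 3.51 ± 1.06 CPM in hair cells (SD, n = 3), had 0.87 ± 0.40 and did not pass. The list had a camera adjusted p = 6.52e-07 and adjusted p = 0.412 with an estimated correlation. Across the 48 members of the 3 hair cell lists that were enriched in hair cells, the median level in supporting cells was a set share of the hair cell mean. It stood at 42.4%, 30.0% and 38.3% in supporting cell replicates 1, 2 and 3. Enrichment needs a log2 fold change over 1, which caps this share, and members such as Ush1c and Eps8 were left out by it.

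Of 26 supporting cell markers, 24 were lower and none higher, with 25 lower adjusted over the list alone. The calcium-binding protein gene S100b changed by -4.62 ± 0.12, Bace2 by -4.31 ± 0.16, Lfng by -3.75 ± 0.12 and the neurotrophin receptor gene Ngfr by -3.58 ± 0.14, with camera adjusted p = 9.18e-10 and adjusted p = 0.412 with an estimated correlation. Of 14 genes of the tectorial membrane and otic matrix, 13 were lower, 13 also adjusted over the list alone: the basement membrane collagens Col4a3 and Col4a4 by -6.12 ± 0.28 and -5.03 ± 0.18, Tectb, a tectorial membrane protein gene, by -3.71 ± 0.15 and Otogl by -2.54 ± 0.16. That list had a camera adjusted p = 9.23e-08 and adjusted p = 0.412 with an estimated correlation.

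Signalling pathways divided by cell type. Of 21 Notch pathway genes, 6 were higher and 12 lower in hair cells, with 6 higher and 13 lower adjusted over the list alone. The ligand genes Dll3, Dll1, Dll4 and Jag2 were higher (1.93 ± 0.14, 1.82 ± 0.16, 1.73 ± 0.17 and 1.44 ± 0.11), and Lfng, the effector genes Hey2 and Hes5 and the receptor gene Notch1 were lower (-3.75 ± 0.12, -2.71 ± 0.21, -2.30 ± 0.34 and -2.44 ± 0.17). As a set with members in both directions it did not pass camera (adjusted p = 0.115, and adjusted p = 0.707 with an estimated correlation) and passed fry as lower in hair cells (adjusted p = 0.00698). Of 15 FGF signalling genes, 11 were lower and 1 higher, with 12 lower and 1 higher adjusted over the list alone. Etv4 and Etv5, transcription factors downstream of FGF receptors, changed by -5.02 ± 0.27 and -2.16 ± 0.20, and Fgfr3 by -2.97 ± 0.09, while the ligand gene Fgf8, which inner hair cells express, was higher by 1.05 ± 0.25. Camera gave adjusted p = 0.00093 for this list, and adjusted p = 0.412 with an estimated correlation. Of 25 Wnt signalling genes, 18 were lower and none higher, with 19 lower adjusted over the list alone. Wnt7a (-3.37 ± 0.11), the secreted Wnt antagonist gene Frzb (-3.08 ± 0.36), Tcf7l2 (-2.51 ± 0.18) and Tcf7l1 (-2.38 ± 0.20) changed most, with camera adjusted p = 8.66e-07 and adjusted p = 0.467 with an estimated correlation.

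Chromatin regulators changed in both directions. Of 20 H3K4 methyltransferase and demethylase genes, 6 were higher and 1 lower, with 4 higher and 1 lower adjusted over the list alone. The H3K4 demethylase gene Kdm1b changed by 0.92 ± 0.10 and Rbbp5, a core subunit gene of the methyltransferase complexes, by 0.56 ± 0.13 (list camera adjusted p = 0.246, adjusted p = 0.535 with an estimated correlation, and fry adjusted p = 0.0057). Of 18 Polycomb and H3K27 demethylase genes, 5 were higher and 3 lower, and the same counts held adjusted over the list alone. Suz12 changed by 0.66 ± 0.07, Cbx2 by -0.88 ± 0.09 and the methyltransferase gene Ezh2 by -0.71 ± 0.10 (camera adjusted p = 0.792, and adjusted p = 0.843 with an estimated correlation). Of 13 acetyltransferase and deacetylase genes, 4 were higher and 3 lower, the same counts adjusted over the list alone, with Hdac5 at 1.13 ± 0.08 and Hdac4 at 1.04 ± 0.11 (camera adjusted p = 0.792, adjusted p = 0.843 with an estimated correlation, and fry adjusted p = 0.0057). Of 25 cell cycle genes, 7 were lower, among them the replication helicase gene Mcm3 (-1.45 ± 0.31), and 1, Ccne2, was higher (5.68 ± 0.324 against 2.22 ± 0.448 CPM, SD, n = 3), the same counts adjusted over the list alone (camera adjusted p = 0.0944, and adjusted p = 0.707 with an estimated correlation).

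The 10 genes with the largest rise in hair cells were Prph2, Neurod6, Wdr63, H2-T23, Hrh3, Dner, Gm11837, Unc80, Armc3 and Gm4724, with log2 fold changes between 2.07 and 2.90. Wdr63, an axonemal dynein gene, averaged 65.1 ± 0.926 CPM (SD, n = 3) in hair cells, and Dner, a Notch ligand relative of neurons, 95.5 ± 10.2 CPM in hair cells and 20.1 ± 2.92 CPM in supporting cells. Prph2, a photoreceptor disc protein gene with a fold change of 2.90 ± 1.01, stood at 21.4 CPM in supporting cell replicate 1 against 0.146 and 0.0789 CPM in the others, and its call was lost in DESeq2 (adjusted p = 0.232) and without 5 of the 6 libraries in turn (adjusted p 0.056 to 0.091), while without supporting cell replicate 1 its log2 fold change was 8.73. The 10 largest falls were Cysltr2, Shisal2b, Col4a3, Adamts15, Smagp, Pkd2l1, Npy, Col4a4, Tal1 and Etv4, between -6.60 and -5.02. The neuropeptide Y gene Npy averaged 202 ± 32.3 CPM in supporting cells and 5.58 ± 1.92 CPM in hair cells, and the polycystin family channel gene Pkd2l1 averaged 166 ± 10.4 and 3.41 ± 1.46 CPM.

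Markers of other cell types were measured beside these. Of 9 glia and Schwann cell genes, 7 were lower in hair cells, 7 also adjusted over the list alone, among them Sox10 (-2.11 ± 0.11), which the supporting cell list also holds (camera adjusted p = 0.00307, and adjusted p = 0.542 with an estimated correlation). Of 10 spiral ganglion neuron genes, 7 were higher, and 8 adjusted over the list alone, among them the neurofilament genes Nefm (1.28 ± 0.08) and Nefl (1.13 ± 0.09, camera adjusted p = 0.00417, and adjusted p = 0.58 with an estimated correlation). In 11 mesenchyme genes 2 were higher, among them Col1a1 (0.97 ± 0.22, call lost in limma-trend on TPM with 0.60, adjusted p = 0.0604), and 4 lower, among them Col1a2 (-1.51 ± 0.43, call lost without hair cell replicate 2, adjusted p = 0.0571, or supporting cell replicate 1, 0.0633), with 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.193, and adjusted p = 0.707 with an estimated correlation). Of 6 endothelial genes 2, Flt1 (-2.97 ± 0.40) and Cdh5 (-2.11 ± 0.62, call lost without hair cell replicate 3, adjusted p = 0.0524, or supporting cell replicate 2, 0.0612), were lower, and 2 adjusted over the list alone (camera adjusted p = 0.193, and adjusted p = 0.707 with an estimated correlation).

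Immediate early and dissociation genes gave 2 higher and 1 lower of 17 and none adjusted over the list alone. Their median log2 fold change was -0.34 and their mean 0.59, with opposite signs, through the heat shock genes Hspa1a (7.34 ± 2.03) and Hspa1b (6.76 ± 1.80), with 3.90 and 3.67 without hair cell replicate 3 and calls lost without supporting cell replicate 3 (adjusted p = 0.0628 and 0.0575), for Hspa1a also without supporting cell replicate 1 (0.0533), and in limma-trend on TPM for both (3.87 and 3.91, adjusted p = 0.155 and 0.124) (camera adjusted p = 0.595 and direction lower, and adjusted p = 0.883 with an estimated correlation). None of 3 red blood cell genes passed (camera adjusted p = 0.792, and adjusted p = 0.843 with an estimated correlation). Of 3 immune genes 1, Cd68, was lower, at 0.707 ± 0.0644 CPM in hair cells, with the call lost in 10 of 11 other settings (adjusted p 0.0551 to 0.197), and none adjusted over the list alone (camera adjusted p = 0.877, and adjusted p = 0.883 with an estimated correlation). The 1 tested melanocyte gene, Pmel, passed only adjusted over the list alone (camera adjusted p = 0.585, and adjusted p = 0.707 with an estimated correlation). Of 3 stria vascularis genes 1, Slc12a2, was higher (0.62 ± 0.10) and 1, Lrp2, lower (-1.01 ± 0.24), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.792, and adjusted p = 0.843 with an estimated correlation). In all, 9 of 21 lists passed camera, none passed with an estimated correlation, and 12 passed fry, which tests whether a list's genes move one way on balance.

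**Figure D1:**
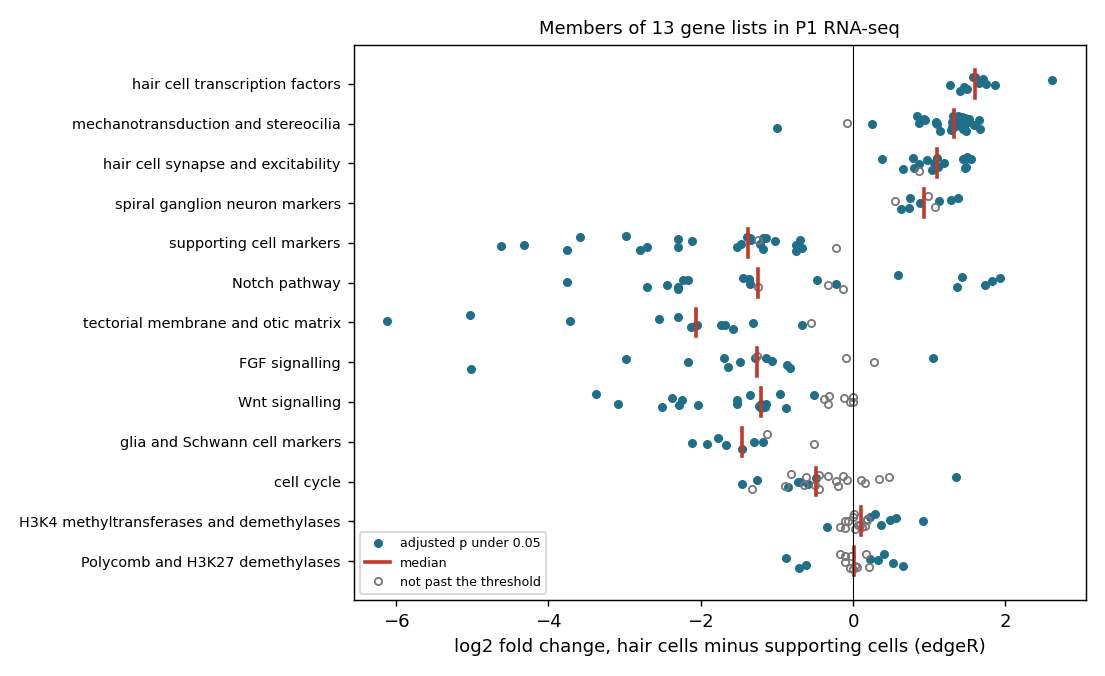
Log2 fold change (x axis, hair cells minus supporting cells at P1, edgeR) of each tested member of the gene lists named on the y axis, a part of the 21 tested. Filled points are past an adjusted p of 0.05, open points are not, and a bar stands at each list's median. All 11 hair cell transcription factors lie above 0, while 24 of 26 supporting cell markers lie below 0 and past the threshold.

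Candidate regulatory elements were then sorted by the cell type in which they were open and active at P1. From 65215 accessible regions of hair cells, 38151 were distal and 5580 of these active, and from 79561 of supporting cells, 56881 were distal and 8262 active. Of these, 679 were hair-cell-specific (median width 219 bp), 3186 supporting-cell-specific (547 bp) and 451 shared (459 bp). Hair-cell-specific elements lay near hair cell genes: of 631 linked to a protein-coding gene, 148 (23.5%) were nearest to a gene enriched in hair cells, against 51 of 418 shared elements (12.2%), a log2 odds ratio of 1.13 (Fisher's exact test, p = 4.09e-06). Of 2575 linked supporting-cell-specific elements, 652 (25.3%) were nearest to a gene enriched in supporting cells, against 36 shared ones (8.61%), a log2 odds ratio of 1.83 (Fisher's exact test, p = 3.7e-16). Among all 21631 annotated genes, 5.53% were enriched in hair cells and 8.40% in supporting cells. The counts of elements depend on the peak lists, since 195 hair-cell-specific elements were left at a -log10 q of 2 or more and 7769 were found without the H3K27ac criterion, a mark measured by different assays in the cell types.

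Of 26 hair cell loci, Srrm4, Myo6, Rbm24, Chrna10 and Pcp4 were nearest to hair-cell-specific elements. At Srrm4, a splicing regulator gene, there were 2 elements inside the gene, on chromosome 5 at 116467169 to 116467563 and 116534189 to 116534607 (mm10), and ATOH1 regions overlapped both. The second carried H3K4me1 in hair cell replicates 1 and 2 and in replicate 2 but not replicate 1 of the E17.5, P1 and P21 utricle supporting cells, and in none of the apical, basal, P6 or P21 cochlear libraries. The element at Rbm24, an RNA-binding protein gene, lay 44.4 kb away on chromosome 13 at 46373597 to 46373709, held an ATOH1 region and had the same pattern of H3K4me1. At Myo6, which encodes a stereocilia base motor, the elements inside the gene on chromosome 9 at 80191673 to 80191790 and 80205746 to 80205950 carried H3K4me1 in every H3K4me1 library. At Chrna10, a region at the gene's end on chromosome 7 at 102111226 to 102111462 carried the mark in hair cells and in both utricle libraries and in no cochlear supporting cell library. Among 16 supporting cell loci, the glutamate transporter gene Slc1a3 had 4 supporting-cell-specific elements, the closest to a gene end 1.71 kb away on chromosome 15 at 8632134 to 8632688, and Sox2, Prox1, Hey1 and Jag1 had 1 each. The Sox2 element lay 16.1 kb from the gene on chromosome 3 at 34668515 to 34668699 and was marked in every H3K4me1 library.

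At P1, H3K4me1 marked 96.5% (95% Wilson interval 94.8 to 97.6) and 96.8% (95.1 to 97.9) of hair-cell-specific elements in the hair cell libraries, a mean of 96.7% ± 0.212 (SD, n = 2). In P1 supporting cells the libraries differed, with 42.1% (38.5 to 45.9) in replicate 1 and 83.5% (80.5 to 86.1) in replicate 2, a mean of 62.8% ± 29.3. Shared elements were marked at 99.3% in hair cells and 98.8% in supporting cells, and supporting-cell-specific elements at 56.7% and 95.2%. Windows moved by 1 Mb were marked at 9.87% to 16.8% in these libraries. The windows reach beyond the elements. ATAC-seq peaks of P1 supporting cell replicates 1 and 2 lay in 43.2% and 10.9% of hair-cell-specific windows (11.8% and 7.22% of moved windows). Marking in supporting cells can therefore come from a neighbouring open region. The log2 odds ratio of hair-cell-specific against shared elements was higher in hair cells by 3.68 (exact permutation test, p = 0.333, adjusted p = 0.467 over 7 comparisons, where 0.33 is the smallest p possible). Without the H3K27ac criterion the odds ratio difference was 1.42, and with the region itself in place of the window it was 3.44. The difference in percentage, 33.8 points, was 13.1 without supporting cell replicate 1 and 54.5 without replicate 2.

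The stages from E17.5 to P21 asked how long supporting cells keep the enhancer mark at hair cell elements. In E17.5 supporting cells, 73.5% and 79.1% of hair-cell-specific elements carried H3K4me1 (mean 76.3% ± 3.96, SD, n = 2), against 24.2% and 33.3% at P6 (28.8% ± 6.43) and 27.5% and 34.0% in the P21 cochlea (30.8% ± 4.60). Shared elements stayed near saturation, with means of 99.7%, 98.8%, 93.8% and 90.3% at E17.5, P1, P6 and P21. Supporting-cell-specific elements were marked at 94.2%, 95.2%, 88.3% and 72.9%. Of 474 hair-cell-specific elements marked in both E17.5 libraries, 249 (52.5%) were marked in neither P6 library, and 2 elements went the opposite way. The same loss applied to 85 of 2936 supporting-cell-specific elements (2.90%) and 7 of 449 shared elements (1.56%). Hair-cell-specific elements were chosen to lack an ATAC-seq peak in P1 supporting cells, and the other sets to be open and active there. The difference in loss between the sets is therefore not independent of that choice. Whether hair cell chromatin in the E17.5 libraries adds to their marking was not tested.

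In percentages, marking of hair-cell-specific elements declined with stage order, with Pearson r = -0.826 from E17.5 to P6 (exact permutation p = 0.0889, n = 6 libraries) and Spearman rho = -0.717 (exact permutation p = 0.178). From E17.5 to P21, r was -0.824 (exact permutation p = 0.0214, n = 8) and rho -0.732 (exact permutation p = 0.0548), with an adjusted exact p = 0.15 over the 7 comparisons. Without the first stage or the last, r was -0.751 and -0.415 to P6 and -0.657 and -0.826 to P21. The odds ratio against shared elements, the measure fixed in advance, gave the opposite sign. Its r was 0.58 to P6 (exact permutation p = 0.222) with rho 0.478 (exact permutation p = 0.4), and 0.832 to P21 (exact permutation p = 0.0135, adjusted 0.0944) with rho 0.781 (exact permutation p = 0.0349). Without the first stage or the last it was 0.386 and 0.815 to P6 and 0.798 and 0.585 to P21. Only 1 to 57 of 451 shared elements were unmarked per library in this series, so that odds ratio moved with few elements, and against supporting-cell-specific elements r was -0.816 to P6 and -0.22 to P21 (exact permutation p = 0.0889 and 0.597). With the 451 shared elements of the definition as worded and every other choice at its main setting, no direction passed adjustment over the 7 comparisons. Among settings that use all libraries, the rise of the odds ratio to P21 passed in 5 others, with adjusted exact p = 0.00556 at a -log10 q of 5 or more, with lists of equal length or with 50% of the window covered, 0.0167 with 250 bp to each side and 0.0389 with another reading of the shared set (566 elements), which was the reading run first. It ranged up to an adjusted exact p = 0.706 without the H3K27ac criterion, and the decline in percentages passed in none. Settings without 1 library were not adjusted. Without P1 supporting cell replicate 2, r of the percentages to P6 was -0.970 (exact permutation p = 0.0667, the smallest possible without that library), and without P6 replicate 2, r of the odds ratio was 0.916 (exact permutation p = 0.0333).

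**Figure D2:**
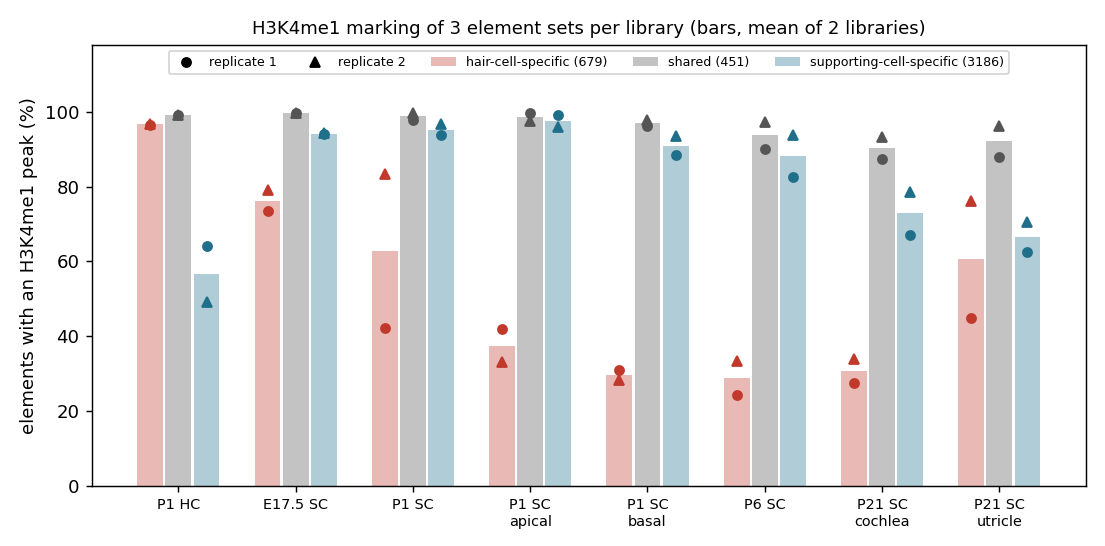
Percentage of elements with an H3K4me1 peak (y axis) in hair cells and in supporting cells of each stage, region and organ (x axis), for hair-cell-specific, shared and supporting-cell-specific elements. Bars are means of 2 libraries and symbols are replicates 1 and 2, with hair-cell-specific elements at 96.7% in P1 hair cells, 76.3% in E17.5 and 28.8% in P6 supporting cells.

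Apical and basal supporting cells of the P1 cochlea, which mature at different times, were compared for the same mark. H3K4me1 marked 42.0% and 33.0% of hair-cell-specific elements in the apical libraries (37.5% ± 6.36, SD, n = 2) and 30.9% and 28.3% in the basal ones (29.6% ± 1.84). Supporting-cell-specific elements were marked at 97.5% and 91.0%, and shared elements at 98.6% and 97.0%. The apical libraries were 7.88 points higher at hair-cell-specific elements (exact permutation test, p = 0.333), and the odds ratio against shared elements was lower by 0.86, written -0.86 as apical minus basal (exact permutation test, p = 0.667, adjusted 0.778). With lists of equal length the percentages differed by 1.47 points, so no difference beyond the spread between libraries was shown.

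The utricle, whose supporting cells were compared with those of the cochlea at P21, held more of the mark at hair cell elements. H3K4me1 marked 44.9% and 76.3% of hair-cell-specific elements in utricle libraries (60.6% ± 22.2, SD, n = 2), against 27.5% and 34.0% in the cochlea. Of the 679 elements, 124 were marked in both utricle libraries and neither cochlear one, and 9 showed the reverse. Shared elements were marked at 92.1% and 90.3% and supporting-cell-specific elements at 66.5% and 72.9% in utricle and cochlea. Against shared elements the log2 odds ratio was higher in the utricle by 1.40 (exact permutation test, p = 0.333, adjusted 0.467), and every utricle library lay above every cochlear one. Without the H3K27ac criterion it was 0.26 (exact permutation test, p = 0.333) and 11.4 percentage points (exact permutation test, p = 0.667), with utricle replicate 1 (26.4%) below cochlear replicate 2 (27.3%). The difference of 29.8 points was 14.1 without utricle replicate 2 and 45.5 without utricle replicate 1.

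Accessibility at P21 was also higher in the utricle lists, in all 3 sets. ATAC-seq peaks overlapped 33.9% ± 6.01 (SD, n = 2) of hair-cell-specific elements in the utricle and 7.51% ± 0.622 in the cochlea, 86.4% and 49.6% of shared elements, and 46.6% and 19.3% of supporting-cell-specific elements. The difference was 26.4 points for hair-cell-specific elements (exact permutation test, p = 0.333) and 12.2 points with lists of equal length. The log2 odds ratio against shared elements differed by -0.05 (exact permutation test, p = 1, adjusted 1). Its sign changed with the setting, with 0.31 at 2 kb or more from gene ends and 0.077 without cochlear replicate 1, so no direction relative to shared elements was shown.

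H3K27me3 showed where Polycomb marked each cell type's genes at P1. At hair-cell-specific elements it was found at 0.737% and 0.442% in hair cells (0.59% ± 0.209, SD, n = 2) and at 6.93% and 8.70% in supporting cells (7.81% ± 1.25). At supporting-cell-specific elements it was found at 15.3% ± 5.09 in hair cells and 1.18% ± 0.0919 in supporting cells, and at shared elements at 0.777% and 0.554%. The log2 odds ratio of hair-cell-specific against shared elements differed by -4.22 (hair cells minus supporting cells, exact permutation test, p = 0.333, adjusted 0.467), and against supporting-cell-specific elements by -7.58 (exact permutation test, p = 0.333). Windows moved by 1 Mb from hair-cell-specific elements were marked at 16.7% and 11.5% in hair cells and 6.49% and 10.0% in supporting cells. From supporting-cell-specific elements they were marked at 14.4% and 8.05% in hair cells and 5.71% and 7.73% in supporting cells. Each set thus lay far below background in its own cell type, where the set was chosen to carry H3K27ac. In the other cell type it lay near background or somewhat above it, with supporting-cell-specific elements at 18.9% and 11.7% in hair cells. Without the H3K27ac criterion the difference in percentage was 0.667 points, with the opposite sign to the -7.23 points found with it.

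At gene ends, where no test was run, the shares were as follows. Of 1741 genes enriched in supporting cells, 70.4% and 58.1% held H3K27me3 within 1 kb of an end in the hair cell libraries and 23.4% and 23.3% in the supporting cell libraries. Of 1172 genes enriched in hair cells, 33.9% and 23.5% held it in hair cells and 42.8% and 43.3% in supporting cells. Of 9951 other genes, 20.1% and 14.1% held it in hair cells and 11.9% and 12.6% in supporting cells. Gene windows moved by 100 kb were marked at 35.3% and 24.2% in hair cells, near the share of hair cell genes there, and at 20.5% and 22.2% in supporting cells, near that of supporting cell genes. Among 26 hair cell loci, 12 were marked in each supporting cell library. Barhl1, Calb2, Espn, Gfi1, Insm1, Lhx3, Pou4f3, Rbm24, Slc17a8 and Srrm4 were marked in both, Hes6 and Tmc1 in replicate 1 alone, and Atoh1 and Otof in replicate 2 alone. In each hair cell library 4 were marked, Calb2, Gfi1, Insm1 and Slc17a8. Among 16 supporting cell loci, 12 and 9 were marked in hair cells, with Gjb2, Gjb6, Hes1, Hey2, Jag1, Prox1, Slc1a3, Sox9 and Sox10 in both libraries, and 4 and 3 in supporting cells. Gjb6 and Prox1 were also marked in both supporting cell libraries, and Lfng was marked in both supporting cell libraries and neither hair cell library.

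H3K4me3, a promoter mark, was read at the ends of 1196 genes enriched in hair cells and 10295 other genes. Hair cell genes were marked at 78.3% and 77.3% in P1 hair cells and at 89.4% and 79.3% in E17.5 supporting cells, by ChIP-seq in both. In supporting cells measured by CUT&RUN, they were marked at 67.8% and 64.0% at P1 and at 61.1% and 56.3% at P6, while other genes stood at 89.2% and 88.4%, and 89.2% and 87.8%. The log2 odds ratio of hair cell genes against other genes was higher by 0.51 in P1 hair cells than in E17.5 supporting cells (exact permutation test, p = 0.333) and differed by -0.39 between P6 and P1 supporting cells (exact permutation test, p = 0.333). In E17.5 replicate 1, 63.0% of windows moved by 100 kb were marked, against 13.8% to 28.3% in the other H3K4me3 libraries. The assay differs between E17.5 and P1 supporting cells, so those stages cannot be told apart from the assay.

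**Figure D3:**
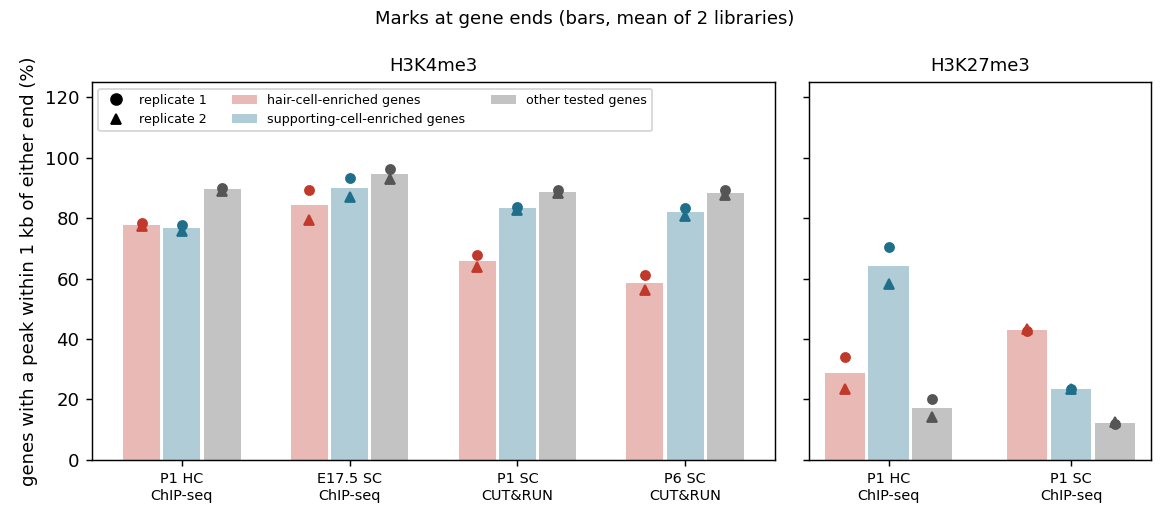
Percentage of genes with a peak within 1 kb of either end (y axis) for genes enriched in hair cells, genes enriched in supporting cells and other genes, for H3K4me3 and H3K27me3 in each cell type and stage (x axis). Bars are means of 2 libraries and symbols are replicates 1 and 2, with H3K27me3 at 70.4% and 58.1% of supporting cell genes in hair cells and 23.4% and 23.3% in supporting cells.

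ATOH1 binding in E17.5 hair cells was set against the element sets. ATOH1 regions found in both libraries, 11173 in all, overlapped 242 of 679 hair-cell-specific elements (35.6%), 225 of 451 shared elements (49.9%) and 33 of 3186 supporting-cell-specific elements (1.04%). Hair-cell-specific against supporting-cell-specific elements had a log2 odds ratio of 5.71 (Fisher's exact test, p = 1.12e-160). Supporting-cell-specific elements were chosen to lack an ATAC-seq peak in P1 hair cells, so their low share bound in hair cells is not independent of that choice. Against shared elements the log2 odds ratio was -0.84 (Fisher's exact test, p = 2.64e-06), and -0.90 and -1.06 with the regions of replicate 1 or 2 alone, so shared elements were bound more often.

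Hair-cell-specific elements with ATOH1 were marked by H3K4me1 more often than those without it in E17.5 supporting cells, and not at P6. At E17.5, 83.5% and 88.0% of the 242 bound elements were marked, against 68.0% and 74.1% of the 437 unbound. At P1 the shares were 47.5% and 39.1% in replicate 1 and 89.3% and 80.3% in replicate 2. At P6, 22.7% and 31.4% of bound and 24.9% and 34.3% of unbound elements were marked. The log2 odds ratios of bound against unbound elements were 1.24 and 1.34 at E17.5, 0.49 and 1.01 at P1 and -0.17 and -0.19 at P6. They declined with stage order (r = -0.959, exact permutation p = 0.0222, the smallest possible for 6 libraries, and rho = -0.956, exact permutation p = 0.0222), with r = -0.931 without the first stage and -0.824 without the last. The test stands outside the family of 7. Whether hair cell chromatin in the E17.5 libraries adds to the higher marking of bound elements was not tested. Without P1 replicate 1 or 2, r was -0.963 and -0.998 (exact permutation p = 0.0667 for each), and with the replicate number as a replicate block it was -0.971 (exact permutation p = 0.0556). Each of these p-values is the smallest that its design can give, so the call could not be tested there.

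**Figure D4:**
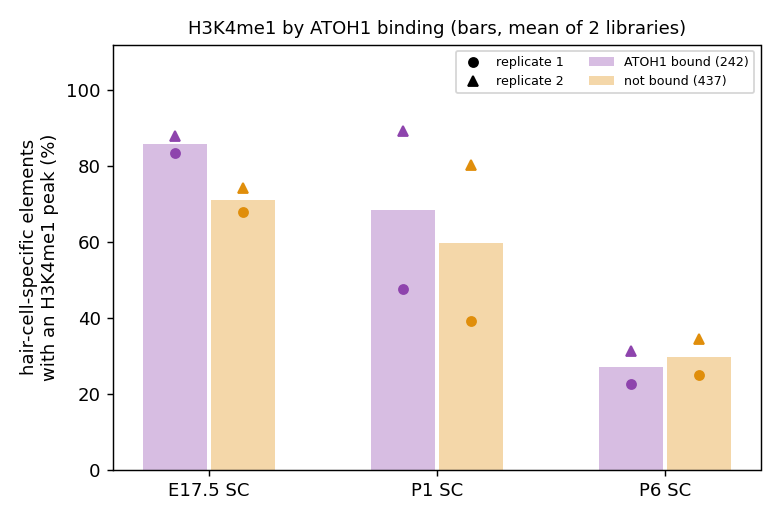
Percentage of hair-cell-specific elements with an H3K4me1 peak (y axis) in E17.5, P1 and P6 supporting cells (x axis), for elements with and without an ATOH1 region. Bars are means of 2 libraries and symbols are replicates 1 and 2, with bound elements at 83.5% and 88.0% at E17.5 and at 22.7% and 31.4% at P6.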

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

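The tests on peak lists of equal length, on the lowest gene ratios and on other splits of the RNA-seq libraries were chosen only after the result was seen.

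The advantage of ATOH1-bound over unbound elements in H3K4me1 differed between stages of supporting cells. The log2 odds ratio was above 0 in both E17.5 libraries (1.24 and 1.34) and below 0 in both P6 libraries (-0.17 and -0.19), and its correlation with stage order was -0.959 (exact permutation p = 0.0222, the smallest possible). At P1 it was 0.49 in replicate 1 and 1.01 in replicate 2, in which hair cell chromatin stays open. ATOH1 was mapped in hair cells, and whether hair cell chromatin in the E17.5 libraries adds to the advantage was not tested. H3K27me3 at hair-cell-specific against supporting-cell-specific elements went opposite ways in P1 hair cells and supporting cells, with a difference in log2 odds ratio of -7.58 (exact permutation p = 0.333, in a design of 2 against 2 libraries that cannot pass a threshold of 0.05). Each set lay far below windows moved by 1 Mb in its own cell type, and near or somewhat above them in the other. The difference therefore rests mainly on the low shares. Each set was chosen to carry H3K27ac in its own cell type, so these low shares are not independent of that choice. Against shared elements the difference was -4.22 with the H3K27ac criterion and -0.94 without it.

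Listed hair cell genes that were enriched in hair cells stood at a similar share of their hair cell level in each supporting cell RNA-seq library (medians 42.4%, 30.0% and 38.3% over 48 genes). The fold change minimum for enriched genes caps this share, so the similarity is in part given by the choice of genes. Among 707 other genes enriched in hair cells, 94.1% had a higher share in supporting cell replicate 1 than in replicate 2, the order of the list medians. Hair cell RNA carried over in 1 proportion per library would give this order, as would any other cause that acts on a whole library. Of 8084 genes with 20 CPM or more in hair cells, 7 were under 20% of that level in supporting cells. Prph2, at 51.9 CPM in hair cells, stood at 21.4, 0.146 and 0.0789 CPM in the supporting cell libraries, so 1 proportion does not hold for every gene. Transcription by supporting cells with Polycomb-marked genes off would leave some genes far lower, and 1.0% of 100 genes with H3K27me3 in supporting cells alone were under 20% of the hair cell level (median 35.1%, against 42.5% for 337 genes without the mark). A peak near a gene end does not show that the gene is off, and gene windows moved by 100 kb were marked at 20.5% and 22.2% in supporting cells. The low count therefore cannot exclude such transcription, and the marked genes had the lower median. Equal mixing in both directions was argued against by the lowest ratios, 30.7% for supporting cells over hair cells and 13.3% for the reverse (1st percentiles, 2.32 times apart). Transcription of hair cell genes by supporting cells stays open. The Lfng reporter gate should remove hair cells. If hair cell RNA was carried over, whether whole cells, free RNA or Lfng-positive cells on the way to hair cells brought it also stays open. In that case the hair cell fold changes may be lower than those between pure cells.

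P1 supporting cell replicate 2 carried H3K4me1 at more hair-cell-specific elements than replicate 1. With lists of equal length the difference was 37.6 percentage points, which argues against the number of peaks as the cause. Coverage and signal were not made equal. The full lists of replicates 1 and 2 covered 85.3 and 143 Mb, with a median -log10 q of 3.73 and 6.65. Against shared elements the log2 odds ratio was alike in both, at -5.85 and -5.90. Regions found in E17.5 supporting cells alone showed no such excess: replicate 2 overlapped 12.3% of 984 and replicate 1 10.2%, a ratio of 1.21. Those regions leave out all that hair cells hold, so they cannot decide on chromatin of an earlier stage at hair cell elements. Of 14071 regions found in hair cells and not in E17.5, apical, basal or P6 supporting cells, replicate 2 overlapped 20.5% and replicate 1 2.21%, a ratio of 9.28. That overlap, not run with lists of equal length, restates the pattern over more regions and would follow from any cause of the marking. Apical and basal libraries of P1 supporting cells marked 42.0% and 33.0%, and 30.9% and 28.3%, of hair-cell-specific elements. They stood nearer to replicate 1 (42.1%) than to replicate 2 (83.5%). Hair cell chromatin in replicate 2 stays open. A difference in coverage or signal between the lists and a biological difference between the cells behind the libraries also stay open and were not tested.

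The same held in part for P21 utricle supporting cell replicate 2. Its lead over replicate 1 was 26.2 percentage points with lists of equal length, so the number of peaks was argued against. Coverage, 73.4 Mb in the full list of replicate 1 and 124 Mb in that of replicate 2, was not made equal. Of 9688 regions found in hair cells and in no cochlear supporting cell library, it overlapped 2541 (26.2%) and replicate 1 823, a ratio of 3.09, which again restates the pattern and does not decide its cause. Hair cell chromatin in replicate 2, a difference in coverage or signal between the lists, and a utricular supporting cell state with these regions marked all stay open. Replicate 1 was also above both cochlear libraries (44.9% against 27.5% and 34.0% of hair-cell-specific elements).

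Of the 10 splits of the 6 RNA-seq libraries into groups of 3, 1, the real one, gave 4104 genes higher and 4121 lower. The other 9 gave 0 past the threshold with edgeR in either direction, and at most 180 higher and 170 lower at an unadjusted p under 0.05. With 10 splits the share cannot be under 0.05, and DESeq2 was not run on the other splits.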

How the results depend on the processing

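Some settings were chosen only after the result was seen. These were percentages combined with another setting, the other reading of the shared set, and the supporting-cell-specific comparison set with lists of equal length. The replicate block for ATOH1-bound elements and H3K4me3 was also chosen then. The counts of genes stayed within 1.5 times under 11 of 12 settings, and a fold change minimum left 1407 higher and 2093 lower. Without 1 library the counts lay between 3279 and 3804 higher and 3483 and 3950 lower. Of 8225 calls, 7429 were shared with DESeq2 and 6409 with limma-trend on TPM, with 1 reversed. Of 911 values of 83 named genes, 866 kept their side of the threshold, 45 lost it and none reversed. Of 21 gene lists, 0 passed camera with an estimated correlation and 12 passed fry. The H3K4me1 contrasts of cell types and of P21 organs kept their direction in 25 settings each, but moved from 3.68 to 1.42 and from 1.40 to 0.26 without the H3K27ac criterion; the cause was not tested. Direction and call were kept for ATOH1 overlap (5) and elements near enriched genes (4). H3K4me3 kept its direction (7 settings for each pair), with 0.51 moving to 0.87 at a -log10 q of 5 or more. Contrasts of 2 against 2 libraries cannot pass a threshold, so only their direction was tested.

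The H3K4me1 trend from E17.5 to P6 (r = 0.58) rose to 0.893 at a -log10 q of 5 or more, 0.771 with equal lengths and 0.842 with 50% of the window covered (exact permutation p = 0.0222 for each), fell to 0.144 at 2 kb or more from gene ends (exact permutation p = 0.756), and lay between 0.246 (without P6 replicate 1) and 0.916 (without P6 replicate 2). It reversed to -0.575 without the H3K27ac criterion, -0.816 against supporting-cell-specific elements and -0.835 against them with equal lengths. As a percentage it was -0.826, with -0.842 at equal lengths, -0.770 without H3K27ac and -0.827 after subtracting supporting-cell-specific elements. Without replicate 1 or 2 the percentage gave -0.815 and -0.778 (E17.5), -0.856 and -0.970 (P1) and -0.742 and -0.781 (P6). The trend to P21 (0.832, adjusted exact p = 0.0944) was 0.939 at a -log10 q of 5 or more, 0.908 with equal lengths and 0.931 with 50% of the window covered (exact permutation p = 0.000794, the smallest possible, adjusted 0.00556 for each) and 0.873 with 250 bp to each side (adjusted exact p = 0.0167). It fell to 0.152 without H3K27ac (exact permutation p = 0.706) and 0.692 at 2 kb or more from gene ends (exact permutation p = 0.0611), lay between 0.771 and 0.953 without 1 library, and reversed to -0.220 against supporting-cell-specific elements and -0.203 with equal lengths. As a percentage it was -0.824, with -0.847 at equal lengths, -0.721 without H3K27ac and -0.619 after subtraction. Without replicate 1 or 2 it was -0.789 and -0.768 (E17.5), -0.864 and -0.889 (P1), -0.841 and -0.820 (P6) and -0.797 and -0.833 (P21). Near saturation of the shared set (1 to 57 of 451 elements unmarked) makes its odds ratio move with few elements; beyond that the cause was not tested.

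Apical minus basal H3K4me1 lay between -1.69 and -0.02 without 1 library and reversed as a percentage: 7.88 points, 1.47 at equal lengths, 9.11 without H3K27ac and 1.32 after subtraction, and 3.39 and 12.4 without apical replicate 1 or 2, 9.21 and 6.55 without basal replicate 1 or 2. Utricle minus cochlea ATAC-seq (-0.05) lay between -0.18 and 0.077 without 1 library (0.077 without cochlear replicate 1) and reversed to 0.0094 with 250 bp to each side, 0.24 with 50% of the window covered, 0.31 at 2 kb or more from gene ends, 0.77 against supporting-cell-specific elements and 0.46 against them with equal lengths. On the negative side, utricle minus cochlea ATAC-seq was -0.49 without H3K27ac and -0.42 at a -log10 q of 5 or more. As a percentage it was 26.4 points, 12.2 at equal lengths, 16.6 without H3K27ac, 30.6 and 22.1 without utricle replicate 1 or 2 and 25.9 and 26.8 without cochlear replicate 1 or 2. After subtracting supporting-cell-specific elements it was -0.94 points. H3K27me3 (-4.22) kept its direction in 24 settings, with -0.94 without H3K27ac, and reversed in 1, 0.667 points without H3K27ac. The causes were not tested, except that a percentage moves with the length of a list. The ATOH1-bound trend lay between -0.998 and -0.941 without 1 library, with exact permutation p = 0.0667 without either P1 library (-0.963 and -0.998), where fewer samples raise the smallest possible p to that value.

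Hair-cell-specific elements numbered 195 and 85 at a -log10 q of 2 and 5 or more, 69693 with a peak in either replicate and 7769 without H3K27ac, by fewer or more peaks. The shared set held 566 elements in the reading that was run first, overlap with a distal and active supporting cell region, which was then replaced by the 451 of the definition as worded. With 566 the trend to P21 was 0.863 (exact permutation p = 0.00556, adjusted 0.0389) and passed adjustment, as did the 4 settings above with the 451, and the trend to P6 was 0.636, with no contrast changing direction.

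With a replicate block, 3934 genes were higher and 4019 lower, and the values were 3.68 (H3K4me1 by cell type), 0.715 (trend to P6), 0.897 (trend to P21, exact permutation p = 0.0139), -0.86 (apical minus basal), 1.40 and -0.05 (utricle minus cochlea, H3K4me1 and ATAC-seq), -4.22 (H3K27me3), -0.971 (ATOH1-bound, exact permutation p = 0.0556, the smallest that this block allows), 0.51 and -0.39 (H3K4me3). Deviations of equal replicate numbers correlated by 0.175, -0.0356 and -0.0448 in RNA-seq, so the numbers are not shown to pair. With 3 libraries per group, 70% of simulated 2-fold changes were found, so smaller changes may be missed, and the read depth of peak lists is not given, so an element without a peak is not shown to lack the mark.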

Other observations

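Several genes near hair-cell-specific elements were outside the lists and were chosen after their values were seen. Anks1, Lnx2, Nfia and Thsd7b were each nearest to 4 such elements. Lnx2, which encodes a ubiquitin ligase that binds Numb, was higher in hair cells by 1.47 (log2), Thsd7b by 1.77, the transcription factor gene Nfia by 0.68 and Anks1 by 0.49. Palld, an actin-binding protein gene, with 3 elements, was higher by 1.66, while Otoa, which encodes a matrix protein that anchors the tectorial membrane, also had 3 elements and was lower in hair cells by a log2 fold change of -0.67. The other genes with 3 elements lay between 0.15 (Arid1b) and 1.52 (Igsf21).

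Of 142 hair-cell-specific elements marked by H3K4me1 in both P6 libraries, 19 (13.4%) were marked in neither P21 cochlear library, and 24 elements were gained. Among 474 marked at E17.5, 17 (3.59%) were marked in neither P1 library and 266 in both, a loss that rests on P1 replicate 2, which marked 83.5% of hair-cell-specific elements against 42.1% in replicate 1. Of 23991 regions found in hair cells and not in apical, basal or P6 supporting cells, the E17.5 libraries overlapped 30.9% and 33.3%. P1 supporting cell replicates 1 and 2 overlapped 6.31% and 33.1%, the P21 cochlear libraries 8.46% and 11.8%, and the utricle libraries 17.3% and 41.9%. The E17.5 libraries thus stood near P1 replicate 2, in which hair cell chromatin stays open. Overlap of replicate lists, as shared over total length, ran from 0.0614 for H3K27ac in hair cells to 0.649 for H3K4me1 in E17.5 supporting cells. Mitochondrial genes took 3.63% to 4.05% of counts in hair cell RNA-seq libraries and 2.54% to 3.00% in supporting cell libraries.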
